A study of Mus musculus with 40 samples.

How the data were processed

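Messenger RNA levels were measured in 40 libraries from 20 adult C57BL/6 mice, 4 on each of days 3, 7, 14, 21 and 42, after the left anterior descending artery of the heart had been tied off for good. Per the labels, total RNA was extracted with an RNeasy Mini column kit and libraries were made with a TruSeq RNA kit from Illumina. Each mouse gave 1 library of the injured region, the fibrotic scar, and 1 of a remote, uninjured region of the same heart. Animal labels start with A on days 3 to 21 and with B on day 42, and a label that recurs on another day is another animal.

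The authors deposited 1 table of RPKM values, reads scaled to gene length and library size, for 11450 genes. STAR, edgeR and the mm10 build are named, per the submitters' processing notes, without versions, settings or the role of each. The annotation and the counting method are not given in the sources used here. Because RPKM are not counts, the tests were run on a log scale. Whole reads were worked back from the steps between low values within a gene: 98.8% of all values lay within 0.01 of a whole number of reads after 1 value per library and 1 per gene had been solved for. There was a median of 563 recovered reads per gene and library. The total of recovered reads over the library size implied by the deposited RPKM is known only relative to 1 library. With the injured library of day 3 mouse A4 set to 1, its median was 1.01 in injured and 1.28 in uninjured libraries. The library sizes behind the deposited values are thus not proportional to the totals of these recovered reads, with a gap between the regions. Reads outside the recovered genes are not in the total. Whether they or a further scaling between libraries made the gap cannot be told. Library medians lay between 5.8 and 6.19 RPKM, 0 pairs of columns were identical, and the highest Spearman correlation between 2 libraries, over genes, was 0.995. Of the symbols, 97.4% matched 1 gene of the GENCODE M21 annotation of mm10, used for positions and gene types.

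Genes with at least 1 RPKM in 4 or more libraries were tested, 11390 in all, on log2(RPKM + 1), a scale that understates the change of low genes. The regions were compared by limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a mean-variance trend and robust moderation in 1 model of all 40 libraries with the mouse as a block (15 residual degrees of freedom), with 1 contrast per day and an F test of whether the difference changed over the days. Days were compared within each region in a model of its 20 libraries (15 residual degrees of freedom), for consecutive days and by an F test over all days. Adjusted p values are Benjamini-Hochberg values over all genes tested, called under 0.05, and errors of log2 changes are standard errors. The mouse pairs the libraries because the series' design text says that both regions came from the same heart. Deviations from the group means of the 2 libraries of a mouse correlated at 0.148 to 0.54. Among the 4 uninjured libraries of its day, each injured library correlated best with its own partner, in 20 of 20 mice. The 2 regions of each mouse agreed in the detection of Xist and Ddx3y in 20 of 20. Xist was at 70.4 to 85.1 RPKM in the injured and 14.1 to 38.9 in the uninjured libraries of 10 mice (1, 2, 3, 2 and 2 mice of the 5 days) and at most at 0.231 in the others.

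Before the data were examined, 33 gene lists were fixed from textbook knowledge: fibrillar collagens, other collagens, collagen processing and cross-linking, non-collagen matrix proteins, matrix proteases and inhibitors, integrin subunits, activated fibroblasts, resting fibroblasts, late scar fibroblasts with cartilage and bone, TGF-beta pathway, neutrophils, monocytes and macrophages, lymphocytes and natural killer cells, dendritic cells and antigen presentation, cytokines and chemokines, interferon-stimulated genes, cell cycle, sarcomere, calcium handling and ion channels, heart stress, oxidative phosphorylation, TCA cycle and fatty acid oxidation, glycolysis, endothelium, pericytes and smooth muscle, lymphatic endothelium, epicardium and mesothelium, adipocytes, Schwann cells and neurons, red blood cells, atrial genes, skeletal muscle and lung. The 32 lists with at least 3 members tested went through camera with a preset correlation of 0.01 between genes, adjusted over lists and comparisons, and again with a correlation estimated from the data. Counts are over the members that were in the deposited table and tested. The table held 0 of 10 lung, 3 of 27 lymphocyte and natural killer cell, 7 of 18 neutrophil and 4 of 13 Schwann cell and neuronal genes. It held 5 of 12 adipocyte and 5 of 10 red blood cell genes, and other lists also lacked members. Only 24 of its genes were below 1 RPKM in all 40 libraries, and how its genes were chosen is not given. The list tests in the uninjured region were added after seeing the data. The log2 ratio of Col5a1 to Col1a1 was compared between regions by a sign-flip permutation test over the 20 mice (100000 resamples) and between days 3 and 42 by an exact permutation test.

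Genes named in the text follow a rule set beforehand. It takes the collagen genes of types I, III and V, and the 8 largest and 8 smallest differences per day among genes past the threshold with at least 5 RPKM in the higher group and 1 direction in 4 of 4 mice. It adds the 5 largest and 5 smallest per step in the injured region with groups that do not overlap, the 8 smallest p of a changing difference, and up to 4 members per list with the largest statistic, leaving out symbols of Gm and Rik models from the ranked sets.

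Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a mean of at least 5 RPKM, median-of-ratios scaling, quantile normalization, limma without trend, no mouse block, the mouse as a random effect, only the libraries compared, a log2 change of at least 1, the animal label as a block across days, an estimated correlation, other collagen pairs and each mouse left out in turn. Added after seeing the data were limma-voom on the recovered reads, scaling to the total of recovered reads, protein-coding genes only, leaving out day 42, and Xist detection as a covariate for the counts between days. It was also fitted for the collagens in the uninjured region from day 21 to 42, where it can change the spread and not the log2 change, because Xist was detected in 2 of the 4 mice of each of these days. The models were tested on simulated data of 11390 genes with 100 genes changed by a log2 value of 2 and 100 by 1. The changed genes were drawn from those with a mean log2(RPKM + 1) above 2, so the shares recovered do not cover lower genes. Far fewer genes were changed than were called in the real comparisons of regions. The noise was drawn for each gene on its own, while real genes vary together, with an estimated correlation of 0.776 within the oxidative phosphorylation list. The false calls of the simulation thus do not tell how many the real data hold. For the difference between regions at 1 day 100% and 98% were recovered with 7 false calls, for a step in the injured region 100% and 97% with 15, for a change over days in that region 100% and 97% with 6, and for a changing difference 100% and 92% with 9. The recovery of reads, tested on 11450 simulated genes, found every read number for 99.8% of them. Tests on single values and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.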

Results

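Injured and uninjured tissue was taken from the hearts of adult C57BL/6 mice, a common inbred laboratory strain, in which the left anterior descending artery, a coronary vessel that feeds much of the left ventricle, had been tied off for good. The scar tissue of the injured region and a region remote from it were dissected from the same heart. With 4 mice on each of days 3, 7, 14, 21 and 42 this gave 40 RNA-seq libraries from 20 mice. The deposited values are RPKM, the authors' reads scaled to the length of the gene and the size of the library. Whole reads could be worked back from the values for 98.4% of the genes, to within 0.01 of a whole number. They summed to between 9785461 and 20072062 reads per library. On the first principal component, which held 75.5% of the variance of the log2 values, all 20 injured libraries lay between -79.2 and -34.64 and all 20 uninjured libraries between 38.47 and 67.44.

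**Figure D1:**
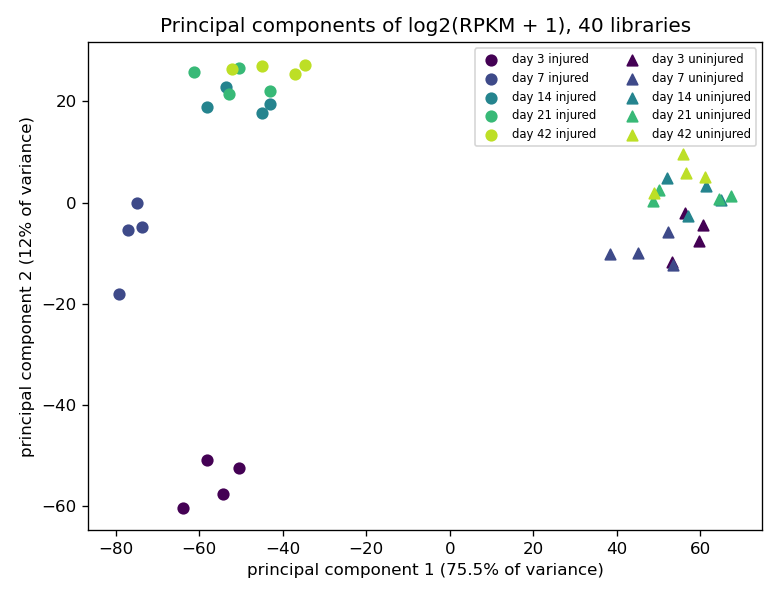
Principal components of log2(RPKM + 1) for the 40 libraries, with the first component (75.5% of the variance) on the x axis and the second (12%) on the y axis, 1 point per library. Circles are injured and triangles uninjured regions, coloured by day after ligation. The regions separate along the first component, and the injured libraries of day 3 lie lowest on the second.

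The study concerned type V collagen in the scar, a minor fibril-forming collagen that is laid down within fibrils of type I collagen. Its chains are encoded by Col5a1 (chromosome 2, 27886425 to 28039514), Col5a2 (chromosome 1, 45374321 to 45503282) and Col5a3 (chromosome 9, 20770050 to 20815067 in the mm10 build, as annotated by GENCODE). Col5a1 stood at 118 ± 14.9 RPKM (SD, n = 4) in the injured region at day 3, peaked at 216 ± 44.1 at day 7, and was at 106 ± 20.5, 93.4 ± 9.63 and 44.9 ± 4.19 at days 14, 21 and 42. In the uninjured region of the same hearts it was between 7.14 ± 3.28 and 16.7 ± 3.7 RPKM. The log2 difference was 2.77 ± 0.20 (SE) at day 3, 3.63 ± 0.20 at day 7 and 2.56 ± 0.20 at day 42. The injured value was above its own uninjured value in 4 of 4 mice on each of the 5 days (limma adjusted p at most 2.65e-10). Col5a2 followed the same course, from 118 ± 9.15 at day 3 to 345 ± 25.3 at day 7 and 105 ± 17.2 RPKM at day 42. Col5a3 had its highest injured value at day 3, 22.3 ± 0.889 RPKM, and had fallen to 10.2 ± 2.36 by day 7 (log2 change of -1.08 ± 0.24, limma adjusted p = 0.000713). Its excess over the uninjured region was 1.86 ± 0.12 on the log2 scale at day 3 and 0.50 ± 0.12 at day 42, where the adjusted p of 0.000749 became 0.0662 with the mouse as a random effect and 0.123 without the mouse in the model.

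The chains of type I collagen, the main scar collagen, and of type III collagen, its early partner, were also higher in the injured region on each of the 5 days. Col1a1 (chromosome 11, 94936224 to 94953042) reached 1020 ± 160 RPKM in the injured region at day 7 against 23 ± 7.91 in the uninjured region, a log2 difference of 5.45 ± 0.31 (limma adjusted p = 3.19e-12). It had dropped to 104 ± 25.7 RPKM by day 42, when the log2 difference was still 4.08 ± 0.31 (limma adjusted p = 3.91e-10). Col1a2 (chromosome 6, 4504814 to 4541544) peaked at 741 ± 83.7 RPKM and Col3a1 (chromosome 1, 45311538 to 45349706) at 1710 ± 79.5 RPKM, both at day 7. From day 7 to day 14 Col5a1 fell by 1.02 ± 0.15, Col1a1 by 1.25 ± 0.21 and Col3a1 by 0.56 ± 0.15 on the log2 scale (limma adjusted p at most 0.00467). Col5a3, at -0.18 ± 0.24, did not pass that step. None of the 6 collagen genes passed the test from day 14 to day 21 (lowest limma adjusted p = 0.253, for Col3a1). All 6 fell from day 21 to day 42, with log2 changes from -0.57 ± 0.12 for Col5a2 to -1.89 ± 0.21 for Col1a1 (limma adjusted p at most 0.00717). Only the mice of day 42 carry B labels, so in both regions this step cannot be told apart from a difference between cohorts. In the uninjured region the 6 genes passed at no step before day 21. From day 21 to day 42 the uninjured Col1a1 fell by 1.62 ± 0.46, Col1a2 by 1.22 ± 0.32, Col3a1 by 0.97 ± 0.32 and Col5a1 by 0.87 ± 0.28 (limma adjusted p = 0.0193, 0.0135, 0.041 and 0.035), while Col5a2 and Col5a3 did not pass. Within day 21 the uninjured Col5a1 level was 8.56 and 8.26 RPKM in mice A3 and A4 against 20.5 and 20.1 in mice A10 and A11. Xist was detected in A10 and A11 and not in A3 and A4. With Xist detection as a covariate, a test chosen after the results were seen, the adjusted p of the 4 genes were 0.0122 (Col1a2) to 0.0336 (Col5a1), and their log2 changes could not move, because 2 of 4 mice had Xist on each of these days. The calls of Col5a1, Col1a1 and Col3a1 ended without any one of the day 21 mice A10 or A11 or the day 42 mice B1, B3 or B9 (adjusted p from 0.0537 to 0.131). Those of all 4 genes ended with only the libraries of these days in the fit (0.0853 to 0.148), with the same log2 changes and a spread taken from fewer libraries. Those of Col5a1 and Col3a1 ended with quantile normalization (log2 changes of -0.75 for each, adjusted p = 0.0521 and 0.115) and with scaling to the total of recovered reads (-0.85 and -0.96, adjusted p = 0.0583 and 0.067). Without day 42 mouse B12 the adjusted p of Col5a2 was 0.0412.

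**Figure D2:**
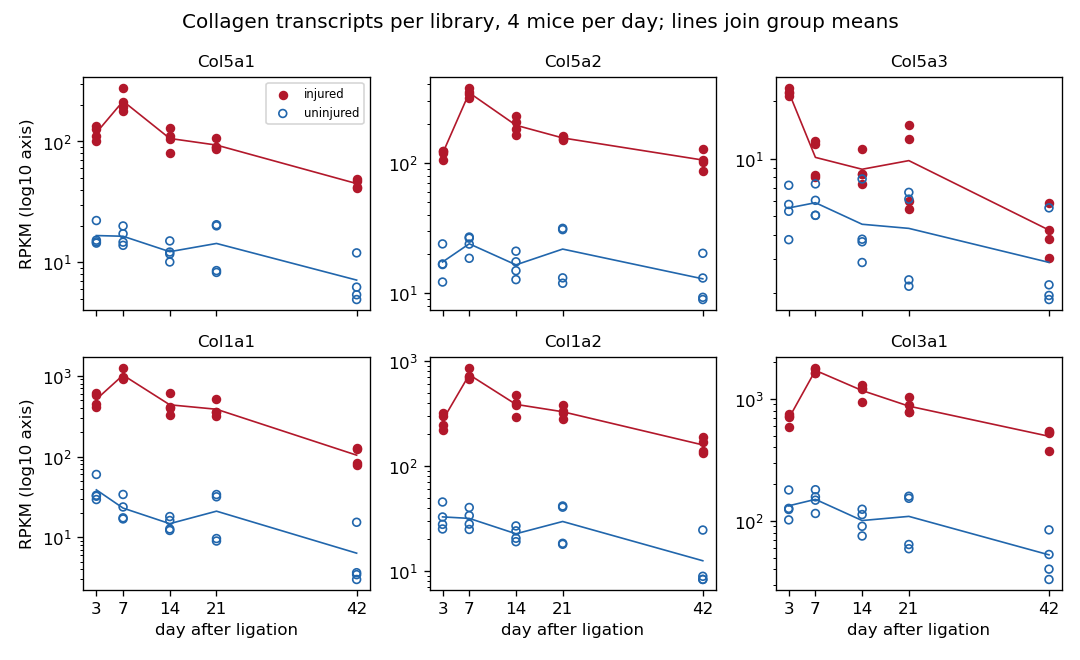
RPKM of 6 collagen genes in each library, on a log10 y axis, against day after ligation, 1 panel per gene. Points are libraries (4 per region and day), filled for the injured and open for the uninjured region, and lines join the group means. Col5a1 rises from a mean of 118 at day 3 to 216 RPKM at day 7 in the injured region and is at 44.9 at day 42.

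A ratio within a library does not depend on the scaling between libraries, so type V was set against type I transcripts as log2(Col5a1/Col1a1). The ratio was lower in the injured than in the uninjured region in 20 of 20 mice, with a mean difference of -1.55 ± 0.418 (SD; two-sided sign-flip permutation test, p = 1e-05, the smallest that 100000 resamples can give). By day the mean difference was -0.93 at day 3, -1.81 at day 7, -1.76 at day 14, -1.61 at day 21 and -1.63 at day 42. Within the injured region the log2 ratio was -2.10 ± 0.126 (SD, n = 4) at day 3, -2.25 ± 0.094 at day 7, -2.02 ± 0.170 at day 14 and -2.02 ± 0.174 at day 21. At day 42 it was -1.18 ± 0.235, higher than at day 3 by 0.919 (two-sided exact permutation test of 4 against 4, p = 0.0286, the smallest possible). The uninjured ratio was -1.17 ± 0.202 at day 3 and 0.448 ± 0.554 at day 42. Set against Col3a1 in place of Col1a1, the mean log2 difference between the regions over the 20 mice was -0.14 (sign-flip permutation p = 0.152). That mean joins days of opposite direction. The ratio to Col3a1 was higher in the injured region in every mouse of day 3 and in all but mouse A12 of day 7. It was lower in every mouse of days 14, 21 and 42, so the pooled test does not show that the regions were alike. In the injured region this second ratio was lower at day 42 than at day 3, with a difference of -0.90 (exact permutation p = 0.0286), the opposite direction to the ratio with Col1a1. Because only the day 42 mice carry B labels, a difference between cohorts cannot be told apart from the later day for either ratio.

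At day 3 Spp1, the matrix protein osteopontin, had the largest excess of the named genes in the injured region, at 907 ± 310 RPKM against 9.04 ± 4.62 (log2 difference of 6.63 ± 0.31). Arg1, the arginase of alternatively activated macrophages, was at 106 ± 53.3 against 1.26 ± 0.874 (5.53 ± 0.34), and Hmox1, which degrades haem, at 290 ± 55.8 against 11.4 ± 2.69 (4.56 ± 0.22). Sprr1a, Adam8 and Lgals3 also stood among the 8 with the largest excess, at 6.19 ± 0.42, 4.51 ± 0.17 and 4.36 ± 0.17. The ribosomal RNA-like models Mir6236 and n-R5-8s1 completed that set, at 4200 ± 5110 and 506 ± 569 RPKM, with an SD above the mean. Among the 8 lowest, Mb, the oxygen store myoglobin, was at 228 ± 93.2 against 7760 ± 481 RPKM (-5.17 ± 0.22) and the muscle creatine kinase Ckm at 19.9 ± 8.48 against 711 ± 90 (-5.17 ± 0.30). Ces1d, Rpl3l, Fndc5, Lrtm1, Dhrs7c and Tcap lay between -5.48 and -4.89. In all, 5021 genes were higher and 4513 lower in the injured region among 11390 tested, 1758 and 1885 of them by a log2 difference of at least 1 (limma, adjusted p under 0.05).

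By group, 7 of the 18 neutrophil genes listed were in the deposited table. All 7 were higher at day 3, among them Csf3r, the receptor of granulocyte colony-stimulating factor, at 12.9 ± 3.75 against 0.617 ± 0.303 RPKM (camera adjusted p = 0.00206, and adjusted p = 0.289 with an estimated correlation). So were 23 of 26 monocyte and macrophage genes, among them Chil3 (3.08 ± 0.09) and Ccr2, the receptor of recruited monocytes (2.83 ± 0.11), while 3 were lower (8.13e-06, and adjusted p = 0.272 with an estimated correlation). Cell cycle genes were higher in 33 of 34 cases, with a median log2 difference of 1.92, and the replication helicase gene Mcm4 stood at 15.7 ± 1.15 against 4.66 ± 0.951 RPKM (8.87e-09, and adjusted p = 0.289 with an estimated correlation). Of 23 endothelial genes 12 were higher and 4 lower, with Cdh5 of endothelial junctions higher (1.15 ± 0.09) and the VEGF receptor gene Kdr lower (-1.11 ± 0.10). As a list they did not pass (camera adjusted p = 0.21, and adjusted p = 0.678 with an estimated correlation). Resting fibroblast genes were lower in 12 of 19 cases, including Gsn (-3.08 ± 0.16), against 5 higher (camera adjusted p = 0.0608, and adjusted p = 0.435 with an estimated correlation). Genes of activated fibroblasts were higher in 20 of 23, with the cross-linking enzyme gene Lox at 3.86 ± 0.20 (0.000286, and adjusted p = 0.351 with an estimated correlation). Every one of the 34 oxidative phosphorylation genes and 37 genes of the TCA cycle and fatty acid oxidation was lower, with medians of -3.14 and -3.09 (1.7e-14 for each, and adjusted p = 0.272 with an estimated correlation for each). The 24 calcium handling and ion channel genes were all lower too, with the potassium channel subunit gene Kcnip2 at -4.86 ± 0.15 (1.09e-09, and adjusted p = 0.272 with an estimated correlation). In the same samples 23 of 25 sarcomere genes were lower and 1 higher (median of -2.65, camera adjusted p = 7.11e-07, and adjusted p = 0.351 with an estimated correlation). Adjusted over the list alone, each of these counts was the same.

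At day 7 Cthrc1, a secreted protein of activated fibroblasts, was at 232 ± 10.3 RPKM against 1.86 ± 0.839 (log2 difference of 6.39 ± 0.31). Fibronectin Fn1 was at 895 ± 129 against 19.9 ± 6.18 (5.46 ± 0.23), and Comp, a protein of cartilage and tendon matrix, at 117 ± 33.9 against 1.04 ± 0.311 (5.83 ± 0.37). Spp1 (6.76 ± 0.31), Thbs1 (5.60 ± 0.28), Gpnmb (5.59 ± 0.22), Ltbp2 (5.44 ± 0.35) and Col1a1 completed the 8 largest. The 8 lowest genes included Ckm (-6.11 ± 0.30), the respiratory chain subunit gene Cox7a1 at 19.7 ± 5.74 against 972 ± 147 RPKM (-5.59 ± 0.19), Ckmt2 (-5.50 ± 0.20) and Myl3 (-5.26 ± 0.23). All 10 fibrillar collagens were higher (median of 3.57; camera adjusted p = 0.000112, and adjusted p = 0.272 with an estimated correlation). So were 39 of 42 non-collagen matrix genes, 22 of 23 activated fibroblast genes and 12 of 14 genes of late scar fibroblasts, cartilage and bone (camera adjusted p at most 0.00198, and adjusted p = 0.272 with an estimated correlation for each of these). The macrophage list had 22 of 26 higher, among them Ms4a7 and Trem2 at 3.86 ± 0.12 and 3.31 ± 0.12 (adjusted p = 0.272 with an estimated correlation). Endothelial genes were lower in 17 of 23, including Pecam1 at 24.1 ± 1.47 against 52.9 ± 2.5 RPKM (-1.10 ± 0.08), with Plvap, a gene of fenestrated vessels, higher at 2.64 ± 0.12 (list camera adjusted p = 0.00289, and adjusted p = 0.359 with an estimated correlation). Cell cycle genes were no longer shifted as a list (4 higher and 9 lower of 34, or 3 and 7 adjusted over the list alone, camera adjusted p = 0.326, and adjusted p = 0.836 with an estimated correlation). For the other lists named, the counts were the same adjusted over the list alone. In total 4961 genes were higher and 4404 lower at day 7 (limma).

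On days 14, 21 and 42 Comp had the largest excess of the named genes, at 385 ± 60.8, 584 ± 93.6 and 529 ± 118 RPKM in the injured region (log2 differences of 6.30 ± 0.37, 5.59 ± 0.37 and 6.18 ± 0.37). Sfrp2, a secreted Wnt modulator, Fmod, a collagen-binding proteoglycan, and Angptl7 stood with it on all of these days, and Angptl7 differed by 4.85 ± 0.28, 5.04 ± 0.28 and 5.73 ± 0.28. Abi3bp and Col8a2 joined at day 21 (4.52 ± 0.17 and 4.58 ± 0.15) and Dkk3 at day 42 (103 ± 6.12 against 4.2 ± 1.7 RPKM). Among the 8 lowest genes were Ckm, at -4.74 ± 0.30 and -4.75 ± 0.30 at days 14 and 42, and Acta1, skeletal alpha-actin, at -5.76 ± 0.48 at day 21. Fibrillar collagens were higher in 10 of 10 genes on each day, with medians of 3.08, 2.66 and 2.46 (camera adjusted p at most 0.000381, and adjusted p = 0.272 with an estimated correlation on each). The late scar, cartilage and bone list had 13 of 14 genes higher on each day, with Runx2, a transcription factor of bone, at 1.33 ± 0.07, 1.45 ± 0.07 and 1.08 ± 0.07 (adjusted p = 0.272 with an estimated correlation on each day). Resting fibroblast genes were higher in 10, 12 and 14 of 19 and lower in 3, 3 and 2, and Tcf21, a transcription factor of cardiac fibroblasts, was at 2.33 ± 0.10 at day 14 and 2.42 ± 0.10 at day 42. That list passed at day 42 (camera adjusted p = 0.00176, and adjusted p = 0.272 with an estimated correlation) and not at days 14 and 21 (camera adjusted p = 0.06 and 0.0504). Epicardial and mesothelial genes were higher in 11 of 12 on each day (camera adjusted p at most 0.0204, and adjusted p from 0.359 to 0.49 with an estimated correlation). The atrial peptide gene Nppa was at 4900 ± 925 against 739 ± 154 RPKM at day 14 and 4460 ± 1140 against 806 ± 468 at day 42. All 34 oxidative phosphorylation genes were lower on each of these days, and their median difference was -2.67, -2.84 and -2.41 (adjusted p = 0.272 with an estimated correlation). The counts of these lists were the same adjusted over the list alone.

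The numbers of genes higher and lower were 4831 and 4608 at day 14, 4906 and 4665 at day 21 and 4611 and 4409 at day 42 (limma). Over the 5 days 3257 genes were higher and 3283 lower in the injured region every time, 1128 were higher on one day and lower on another, and 199 were called on no day. With values rescaled to the total of recovered reads, the median log2 difference of all genes was between 0.223 at day 7 and 0.407 at day 3, against 0.0271 to 0.0554 as deposited. The share of calls that were higher was then 69.3%, 62.3%, 66.4%, 66.7% and 69.9% at days 3, 7, 14, 21 and 42, against 52.7%, 53%, 51.2%, 51.3% and 51.1% as deposited. Of the 209 list tests called in all comparisons, 0 had a median that changed sign under 3 other scalings. Of 160 list tests between regions 65 were higher and 37 lower with the preset correlation of 0.01, and 0 held with an estimated correlation.

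**Figure D3:**
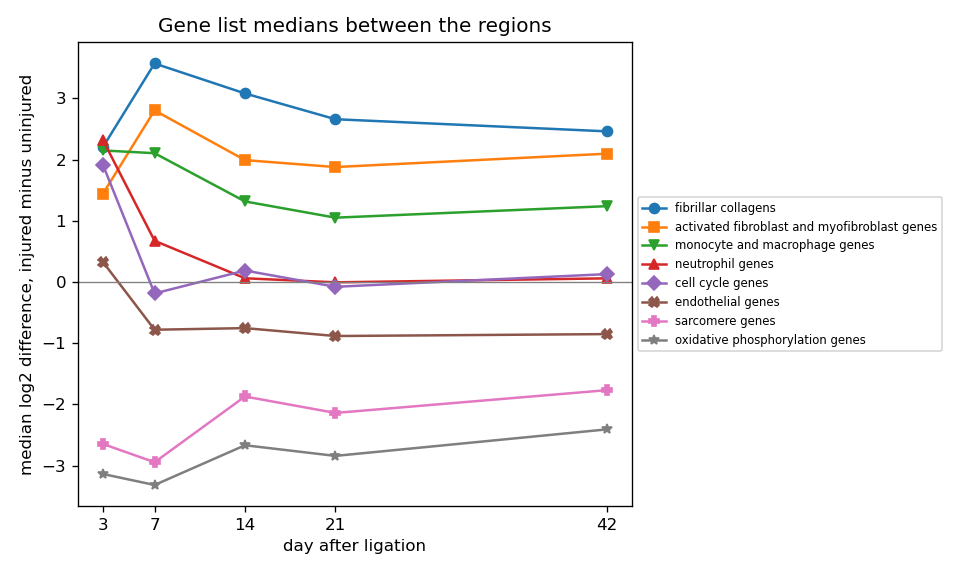
Median log2 difference between the injured and uninjured region over the tested members of 8 gene lists (y axis) at days 3, 7, 14, 21 and 42 after ligation (x axis), 1 line per list; the line at 0 marks no difference. Cell cycle genes stand at a median of 1.92 at day 3 and -0.19 at day 7, and oxidative phosphorylation genes are at or below -2.41 on every day.

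The difference between the regions changed over the 5 days for 8460 of 11390 genes (limma F test of the interaction, adjusted p under 0.05). Fbln1, a matrix fibulin, had the smallest p (adjusted p = 1.51e-13): it was lower in the injured region at day 3 (-1.04) and higher from day 7 on, by 2.11, 2.95, 3.21 and 3.47. Fbln5, an elastic fibre protein, went from -0.33 at day 3 to 3.33 at day 7 and C1ra, a complement protease, from -0.51 at day 3. Sh2d5 and Chil3 went from 2.70 and 3.08 at day 3 to 0.20 and 0.03 at day 14. Pcsk6 went from -1.69 at day 3 to 0.80 at day 42, and Ctsf, a lysosomal protease gene, from -2.78 to -0.56. Between consecutive days the difference changed for 5221 genes from day 3 to 7, 2659 from day 7 to 14, 0 from day 14 to 21 and 1457 from day 21 to 42. From day 14 to 21, 619 genes had an unadjusted p under 0.05, near the share of 0.05 that chance gives.

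Within the injured region 9977 genes changed over the days (limma F test), and of these 3680 had their highest mean at day 3, 1722 at day 7, 608 at day 14, 1446 at day 21 and 2521 at day 42. From day 3 to day 7, 3160 genes rose and 3720 fell. C1qtnf3 went from 0.104 ± 0.0588 to 57.5 ± 27.2 RPKM (log2 change of 5.59 ± 0.36), Comp rose by 5.28 ± 0.18, elastin Eln by 5.01 ± 0.33, Fmod by 4.85 ± 0.20 and Col8a2 by 4.23 ± 0.20. The monocyte-attracting chemokines Ccl2 and Ccl7 fell by 2.94 ± 0.26 and 2.91 ± 0.27, Arg1 by 3.21 ± 0.52, and the mitochondrial transcripts mt-Ti and mt-Nd6 by 3.51 ± 0.35 and 2.82 ± 0.48. Non-collagen matrix genes rose in 35 of 42 (36 adjusted over the list alone), a list call that held with an estimated correlation (adjusted p = 0.0313). All 34 cell cycle genes fell, with Mcm5 at -1.64 ± 0.12 (camera adjusted p = 5.53e-16, and adjusted p = 0.429 with an estimated correlation). The fall of 6 of 7 neutrophil genes (7 adjusted over the list alone) had an adjusted p = 0.449 with an estimated correlation, and 19 of 23 endothelial genes fell, Nos3 by 1.39 ± 0.12 (adjusted p = 0.449 with an estimated correlation). Resting fibroblast genes rose in 12 of 19 (13 adjusted over the list alone), Dpt from 26.9 ± 2.63 to 163 ± 12.9 RPKM (adjusted p = 0.273 with an estimated correlation).

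From day 7 to day 14, 2496 genes rose and 2416 fell. The balance turned with the scaling: 2278 rose and 2578 fell with quantile normalization, against 2904 and 2105 with median-of-ratios scaling. Sarcomere genes rose in 24 of 25, with Myh7, the slow myosin heavy chain of the stressed heart, going from 25.8 ± 11.5 to 352 ± 124 RPKM (3.80 ± 0.38). The oxidative phosphorylation genes rose in 34 of 34 (adjusted p = 0.449 with an estimated correlation for both lists). Cytl1, Angptl7, Myoc and Fmo2 rose by 3.60 ± 0.22, 3.16 ± 0.43, 2.97 ± 0.30 and 2.51 ± 0.43. Macrophage genes fell in 21 of 26, with Spp1 falling from 363 ± 196 to 38.3 ± 16.3 RPKM. Activated fibroblast genes fell in 19 of 23 (with 1 rising adjusted over the list alone), with Tnc at -2.23 ± 0.22 (adjusted p = 0.351 and 0.363 with an estimated correlation). Cell cycle genes fell again in 30 of 34 (31 adjusted over the list alone), Mki67 from 13.3 ± 2.31 to 5.22 ± 0.489 RPKM (adjusted p = 0.447 with an estimated correlation). H19, Cemip and Serpinb1a fell by 2.73 ± 0.30, 2.67 ± 0.44 and 2.65 ± 0.21. From day 14 to day 21, 0 genes passed (limma), and 0 with limma-voom on the recovered reads. An unadjusted p under 0.05 (limma) was found for 1496 of 11390 genes, above the share of 0.05 that chance gives for independent genes. Without day 14 mouse A5, 21 genes were higher and 4 lower, without day 21 mouse A4 1 was lower, and without day 21 mouse A11 1 was higher. As lists, 2 were higher and 5 lower at this step by camera, with small medians, and 0 held with an estimated correlation. The lowest adjusted p were those of cell cycle genes (median of -0.20, 0 of 34 lower or 9 adjusted over the list alone, 3.72e-10, and adjusted p = 0.449 with an estimated correlation), endothelial genes (median of -0.17, 0 of 23 lower or 1 adjusted over the list alone, 0.000333, and adjusted p = 0.449 with an estimated correlation) and interferon-stimulated genes (median of 0.14, 0 of 22 higher, also adjusted over the list alone, 0.00227, and adjusted p = 0.637 with an estimated correlation).

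From day 21 to day 42, 1281 genes rose and 1544 fell, few of them by a log2 change of at least 1 (20 and 31). Of the fibrillar collagens 7 of 10 fell, 12 of 20 other collagens, among them Col15a1 by 1.03 ± 0.12, and 15 of 42 non-collagen matrix genes, among them the perlecan gene Hspg2 by 1.35 ± 0.12 (adjusted p = 0.447, 0.351 and 0.273 with an estimated correlation). Adjusted over the list alone these counts were 8, 13 and 16. Nexn, mt-Nd2, F13a1, mt-Nd1 and Mgl2 had the largest rises, from 0.94 ± 0.25 to 1.22 ± 0.31. The small RNAs Rny3 and Vaultrc5 fell most, Rny3 from 256 ± 44.5 to 30 ± 11 RPKM; the day 42 mice carry another letter in their labels than the mice of the other days. Of the 128 list tests between days in this region 23 were higher and 30 lower, and 1 held with an estimated correlation. Random assignments of the mice to the days called at least as many lists in 33 of 100 draws.

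**Figure D4:**
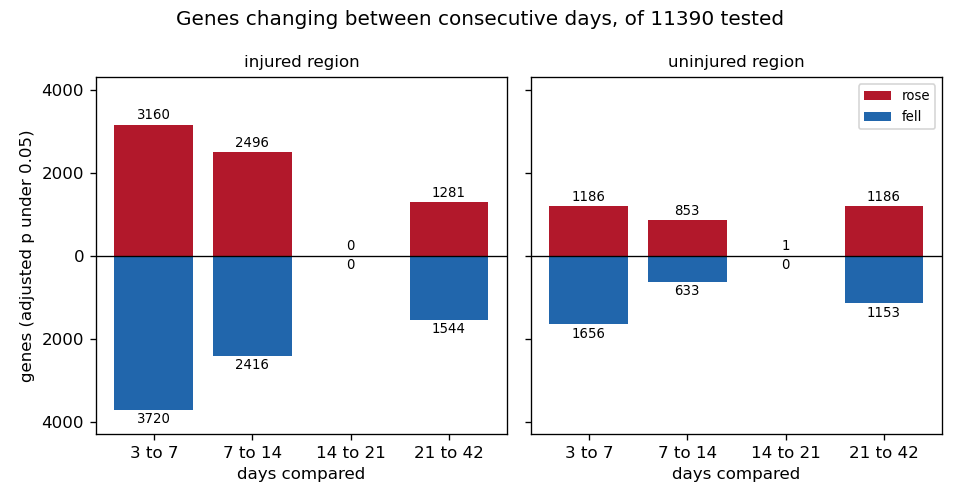
Genes that rose (bars above 0) and fell (bars below 0) between consecutive days, in the injured and the uninjured region, by limma at an adjusted p under 0.05. Bars are counts of genes out of 11390 tested; from day 14 to day 21 they are 0 in the injured region and 1 in the uninjured region.

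The uninjured region changed over the days for 5375 genes (limma F test). From day 3 to day 7, 1186 genes rose and 1656 fell. Cell cycle genes rose in 29 of 34 (30 adjusted over the list alone), while in the injured region of the same hearts they fell. The spindle motor gene Kif11 went from 2.32 ± 0.828 to 7.95 ± 1.93 RPKM and was at 1.39 ± 0.473 at day 14. From day 7 to day 14, 28 of 34 fell again (30 adjusted over the list alone), with adjusted p = 0.526 and 0.501 with an estimated correlation for the rise and the fall. Interferon-stimulated genes went the same way, with 16 of 22 rising to day 7, Rsad2 from 5.38 ± 1 to 12.4 ± 2.23 RPKM, and 12 falling to day 14 (18 and 19 adjusted over the list alone, and adjusted p = 0.501 with an estimated correlation for both). Genes of the TCA cycle and fatty acid oxidation fell in 20 of 37 from day 3 to day 7 (31 adjusted over the list alone), the fatty acid transporter gene Slc27a1 by 1.02 ± 0.14. In the same step 16 of 24 calcium handling and ion channel genes fell, Ryr2 by 0.59 ± 0.10 (18 adjusted over the list alone, and adjusted p = 0.578 and 0.501 with an estimated correlation for the 2 lists). Random assignments of the mice to the days called at least as many lists in this region in 15 of 100 draws. Without day 7 mouse A7 the counts of this step were 781 and 924, without day 3 mouse A8 931 genes fell, and scaling to the total of recovered reads gave 2571 higher and 587 lower (81.4% higher against 41.7%).

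From day 7 to day 14, 853 genes rose and 633 fell in the uninjured region, and both counts moved with single mice. They were 271 and 357 without day 7 mouse A7, 259 and 357 without day 7 mouse A12, 301 and 382 without day 14 mouse A5, and 244 and 369 without day 14 mouse A6. Scaling to the total of recovered reads gave 291 higher and 1015 lower, a share of 22.3% higher against 57.4% as deposited, and quantile normalization gave 45.4%. With Xist detection as a covariate 1493 genes were higher. From day 14 to day 21, 573 genes had an unadjusted p under 0.05 (limma), near the share of 0.05 of the genes tested that chance gives. The count of genes that passed was 1 (limma), and also 1 with limma-voom. That count was 0 without any one of day 14 mice A4, A6 and A11 or day 21 mice A3, A4 and A10. As lists, 12 were higher and 1 lower at this step, the macrophage list with the lowest p (median of 0.14, 0 of 26 higher, also adjusted over the list alone, camera adjusted p = 1.29e-05, and adjusted p = 0.576 with an estimated correlation), and 0 held with an estimated correlation. From day 21 to day 42, 1186 genes rose and 1153 fell, and the laminin gene Lamb1 fell by 0.53 ± 0.08 (limma adjusted p = 0.000109). Without day 42 mouse B9 645 genes fell at that step. The share of its calls that were higher was 50.7% as deposited, 60.2% with quantile normalization, 55.1% with scaling to the total of recovered reads and 43.9% with median-of-ratios scaling. As lists, 0 were higher and 15 lower, with the lowest p for non-collagen matrix genes (median of -0.51, 12 of 42 lower or 13 adjusted over the list alone, camera adjusted p = 9.52e-07, and adjusted p = 0.614 with an estimated correlation), and 0 held with an estimated correlation.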

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

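The tests of one repeat family, of small RNA recovery, of non-coding models and of other groupings of the mice were chosen after the results were seen. Of 178 groups of 4 libraries that were tested for a far value, 15 held a library past the 0.05 limit of Dixon's test, and chance gives about 1 in 20 such groups.

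In the uninjured region, day 42 mouse B12 stood above the other 3 mice in Col1a1 (15.3 RPKM against 3 to 3.64), Col1a2 (24.5 against 8.29 to 8.89) and Col5a3 (5.54 against 1.84 to 2.2). Day 3 mouse A7 stood above in uninjured Col1a1 (60 against 29.3 to 33.1) and Col5a1 (22.2 against 14.4 to 15.3). Where the remote pieces lay relative to the scar is not in the labels and was not tested. In the injured region day 7 mouse A10 was at 1258 RPKM of Col1a1 (922 to 962 in the others) and 654 of Spp1 (236 to 303), and day 21 mouse A10, another animal, at 108 of Col5a1 (86.5 to 90). Day 42 mouse B1 was lower in injured Col3a1 (374 against 519 to 542) and in S100b (3.89 against 5.44 to 5.75). Comp was at 167 RPKM in injured day 7 mouse A12 (95 to 105 in the others) and at 705 in day 42 mouse B12 (458 to 483). Uninjured Csf3r was at 1.07 in day 3 mouse A8 (0.437 to 0.494), uninjured Kif11 at 5.05 in day 7 mouse A9 (8.74 to 9.02), and Mir6236 at 11790 in injured day 3 mouse A5 (877 to 2665).

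The difference between the regions changed over the 5 days for 8460 genes by the limma F test of the interaction. Random draws of the mice into the days called as many in 1 of 100 draws, the real one included, and at most 1439 in the others. Among the collagens the adjusted p of this test was 0.0169 for Col5a1, 0.00777 for Col5a2, 7.59e-06 for Col5a3, 0.0147 for Col1a1, 0.00417 for Col1a2 and 0.01 for Col3a1. For the 8 genes with the smallest p it was 1.51e-13 (Fbln1), 3.25e-13 (Sh2d5), 3.5e-13 (Chil3), 6.67e-13 (Pcsk6), 1.23e-12 (Fam180a) and 1.46e-12 (Ctsf, C1ra and Fbln5).

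Higher matrix and lower cardiomyocyte transcripts in the injured region could come from a lower share of cardiomyocytes alone, which would raise the markers of all other cell types alike. The macrophage and endothelial medians at day 7 were instead 2.11 and -0.78, a gap of 2.88 on the log2 scale (permutation of the 49 genes, p = 4e-05). That p takes the genes as independent, though their estimated correlation was 0.3166 and 0.2902 within the lists, so it overstates the evidence. As lists neither passed with an estimated correlation (camera adjusted p = 0.272 and 0.359). By limma over the mice 22 of 26 macrophage genes were higher and 3 lower, and 17 of 23 endothelial genes lower and 3 higher. These opposite directions argue against a lower share of cardiomyocytes as the whole account. The scaling between libraries is argued against for the fibrillar collagens, whose median was at least 2.19 under 4 scalings on each of the 5 days. For the sarcomere genes the median nearest to 0 was -0.72, with quantile normalization at day 42, short of the bound of -1 set beforehand, so a part played by the scaling cannot be excluded there. A change in the expression of the cells themselves and a change in cell types after injury stay open, and cannot be separated in whole tissue.

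At day 3 the 12 satellite-like gene models, picked by position or symbol and not by gene type, were higher in the injured region. Their median difference was 5.25 on the log2 scale, with summed levels of 5090 to 31900 RPKM against 17 to 247. Their log2 values over the 20 injured libraries correlated at a median Pearson r of 0.984 between pairs of models. Injured sums were 52.3 to 186 RPKM at day 21 and 807 to 1240 at day 42, when uninjured sums were 266 to 763. The shared rise at day 3 thus gives a high correlation by itself. Whether they are reads of one repeat family counted under several models thus cannot be told from it. Carry-over of genomic DNA is a candidate source: the single-exon and intronic models that DNA would also raise had a median difference of 0.79, with 135 of 180 higher and 23 lower. Of all 11390 genes tested at day 3, 5021 were higher and 4513 lower, with a median difference of 0.0554. Transcription of the repeats in the injured tissue was not tested and stays open.

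From day 21 to day 42, 682 genes were called in both regions, 655 of them in 1 direction, against an overlap of 580 for independent lists. The 2 lists are not independent, because both regions come from the same mice, whose deviations correlated at 0.148 to 0.54 between regions, so shared deviations of the mice alone could raise both counts. The 29 small non-coding RNA models had a median log2 change of -1.17 in the injured and -1.41 in the uninjured region, so that small RNA recovery may differ between the B-labelled and A-labelled mice. Protein-coding genes made up 93.8% of the injured calls, so other models alone did not make up the count, and too few of them were tested to do so. Of the genes tested 93.8% were protein-coding as well, so that this share says nothing else on the source of the count. A difference between the cohorts cannot be told apart from the later day, because all mice of day 42 and no others carry B labels.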

How the results depend on the processing

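The alternatives of limma-voom, scaling to the total of recovered reads, protein-coding genes only, leaving out day 42 and the Xist covariate were added after seeing the data. Over all alternatives, 514 counts of genes stayed within 1.5 times the reported count and 74 did not. Counts of lists did so in 120 of 124 cases, and 28031 values of named genes kept direction and side of the threshold, while 741 lost and 188 gained a call. No count moved by over 1.5 times with the pseudocount of 0.1, no filter, median-of-ratios scaling, limma without trend, the random effect, limma-voom, protein-coding genes only or without day 42. Where no reason is given below, the cause was not tested.

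Without the mouse as a block the paired comparisons called 4939 higher and 4438 lower genes at day 3, 4861 and 4329 at day 7, 4739 and 4524 at day 14, 4811 and 4590 at day 21 and 4493 and 4337 at day 42, with 8013 changing differences and 63 higher and 33 lower lists. The call of Col5a3 at day 42 (0.50) ended without it (limma adjusted p = 0.123) and also with the mouse as a random effect, which keeps the pairing (0.0662). With the animal label as a block across days 14 and 21, which pairs different animals, 23 genes were higher and 10 lower in the injured region and 0 higher in the uninjured region.

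With a mean of at least 5 RPKM, which tests fewer genes, 2367, 2385, 2162, 2174 and 2162 genes were higher and 3409, 3370, 3619, 3680 and 3419 lower at days 3 to 42, so that lower genes outnumbered higher ones. In this set 5106 differences changed, and 6042 injured and 3497 uninjured genes changed over the days. Injured counts were then 1816 higher and 2292 lower for days 3 to 7, 1332 lower for days 7 to 14, 2 higher and 1 lower for days 14 to 21 and 918 lower for days 21 to 42. Uninjured counts were 657 higher for days 3 to 7, 263 lower for days 7 to 14 and 522 higher for days 21 to 42. A log2 change of at least 1, a stricter call by construction, left 1758 higher and 1885 lower at day 3, 1594 and 1806 at day 7, 1410 and 1715 at day 14, 1530 and 1792 at day 21 and 1170 and 1505 at day 42. For the steps it left 412 and 399, 272 and 180, and 20 and 31 in the injured region (days 3 to 7, 7 to 14, 21 to 42) and 80 and 13, 16 and 92, 0 higher (days 14 to 21), and 123 and 31 in the uninjured region.

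In the uninjured region from day 7 to 14, 519 genes were higher with quantile normalization and 1493 with the Xist covariate. With only the libraries compared, 0 were higher for days 14 to 21 and 625 lower for days 21 to 42. Scaling to the total of recovered reads gave 2882 lower genes at day 42, 2571 higher and 587 lower in the uninjured region for days 3 to 7, and 291 and 1015 for days 7 to 14. An estimated correlation left 0 higher and 0 lower lists between regions and 1 and 0 between days in the injured region. With Col3a1 in place of Col1a1 the difference of the ratio between regions was -0.14 (permutation p = 0.152), a mean over days of opposite direction, and that of day 42 from day 3 reversed to -0.90. With Col5a2 over Col1a2 they were -0.57 (permutation p = 1e-05) and 0.60 (exact permutation p = 0.0286), the same directions as with Col5a1 over Col1a1. The uninjured falls of Col5a1 and Col3a1 from day 21 to 42 lost their calls with quantile normalization (limma adjusted p = 0.0521 and 0.115) and with scaling to the total of recovered reads (0.0583 and 0.067).

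Leaving out each mouse in turn, the uninjured counts ran from 781 to 1180 higher and 924 to 1655 lower (days 3 to 7), 244 to 1058 and 357 to 749 (days 7 to 14), 0 to 1 higher (days 14 to 21) and 645 to 1593 lower (days 21 to 42), and the injured counts from 0 to 21 higher and 0 to 4 lower (days 14 to 21).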

Other observations

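Tests of other groupings of the mice, given last here, were chosen after the results were seen. Beyond the fibrillar collagens, the enzymes that process collagen were higher in the injured region in 26, 25, 23, 21 and 23 of 28 genes on days 3 to 42 and lower in 1, 2, 4, 3 and 3 (2 lower at day 3 adjusted over the list alone, otherwise the same). Lox, which cross-links collagen, stood at 346 ± 40.9 against 7.27 ± 1.24 RPKM at day 7 and at 64.6 ± 15.2 against 2.26 ± 1.36 at day 42 (SD, n = 4). Camera adjusted p values of this list were at most 0.000358, and adjusted p = 0.272 to 0.351 with an estimated correlation. Other collagens were higher in 14 of 20 genes at day 3 and in 17 to 19 later, among them the basement membrane collagen gene Col18a1 at day 3 (2.80 ± 0.12) and Col8a2 at day 7 (41 ± 4.99 against 0.824 ± 0.507 RPKM), with adjusted p = 0.272 to 0.562 with an estimated correlation. Matrix proteases and inhibitors were higher in 21 to 25 of 29 genes, with the lysosomal protease gene Ctss at 564 ± 59.4 against 32 ± 3.84 RPKM at day 7, and Mmp15 was lower at day 42 (-2.32 ± 0.11), with adjusted p = 0.272 with an estimated correlation on each day. Integrin subunits were higher in 13 to 15 of 19 genes, with Itgb3 at 9.89 ± 0.885 against 0.836 ± 0.137 RPKM at day 3, and TGF-beta pathway genes in 21, 24, 24, 25 and 26 of 27, with the ligand gene Tgfb3 at 104 ± 6.33 against 10.5 ± 1.75 at day 7 (adjusted p = 0.272 with an estimated correlation for both lists on each day).

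Antigen presentation genes were higher in 9 of 9 on all 5 days, with the class II gene H2-Ab1 at 81.9 ± 7.56 against 14.9 ± 2.36 RPKM at day 7 (camera adjusted p at most 0.0054, and adjusted p = 0.272 to 0.359 with an estimated correlation). Cytokines and chemokines were higher in 15 of 17 at day 3 (camera adjusted p = 0.000601, and adjusted p = 0.272 with an estimated correlation), and their list did not pass on the other days (camera adjusted p = 0.0529 to 0.476). Interferon-stimulated genes were higher in 20 of 22 at day 3, Mx1 by 1.69 ± 0.14 (adjusted p = 0.515 with an estimated correlation), and did not pass as a list later. Of the 27 genes of the lymphocyte list only the immunoglobulin genes Ighm, Igkc and Jchain were in the deposited table: 0 of 3 passed at day 3 and 3 of 3 were higher at days 7 and 14, while the list passed on no day (camera adjusted p at least 0.169). Glycolysis genes were lower in 15, 16, 17 and 15 of 22 from day 7 on, with muscle enolase Eno3 at 18.7 ± 1.88 against 646 ± 86.4 RPKM at day 7 (adjusted p = 0.43 to 0.476 with an estimated correlation). At day 3 that list did not pass (7 higher and 12 lower, camera adjusted p = 0.291), and its median of -0.59 became 0.15 with quantile normalization, with the lactate transporter gene Slc16a3 higher (3.08 ± 0.11) and the glucose transporter gene Slc2a4 lower (-4.41 ± 0.15). Adipocyte genes were lower in 4 of 5 at day 3 and 5 of 5 later (adjusted p = 0.272 to 0.289 with an estimated correlation), Schwann cell and neuronal genes higher in 4 of 4 from day 14, Ncam1 by 2.69 ± 0.10 at day 42 (adjusted p = 0.272 with an estimated correlation), and red blood cell genes lower in 5 of 5 from day 7, Hbb-bs by -2.82 ± 0.26 at day 7 (adjusted p = 0.359 to 0.43 with an estimated correlation). The lists of heart stress, pericyte and smooth muscle, lymphatic endothelial, atrial and skeletal muscle genes passed on no day (camera adjusted p at least 0.34, 0.294, 0.107, 0.0993 and 0.326). Their members went both ways: at day 3 the pericyte gene Abcc9 was at -2.72 ± 0.11, the podoplanin gene Pdpn at 2.38 ± 0.14 and the lymphatic regulator gene Prox1 at -2.23 ± 0.14.

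Other groupings of the libraries were counted for each comparison. Within a day, exchanging the regions of whole mice gives 8 splits, too few for a share under 0.05. The real split called 9534, 9365, 9439, 9571 and 9020 genes at days 3, 7, 14, 21 and 42, the only 1 of the 8 with so many, and the highest other split 0, 0, 0, 3990 and 8, where the 3990 came from exchanging the regions of day 21 mouse A11. For consecutive days there are 35 splits of 8 libraries. The real split was the 1 with the most calls in the injured region from day 3 to 7 (6880 against at most 1711), day 7 to 14 (4912 against 1361) and day 21 to 42 (2825 against 512). So it was in the uninjured region for the same steps (2842 against 167, 1486 against 226 and 2339 against 890). For these 6 the share was 1 of 35, the smallest possible, and it was not adjusted over the steps. Chance was excluded for them only by the 0.05 threshold on single steps. From day 14 to day 21 it was not excluded in the uninjured region, where 4 of 35 splits called at least the real 1 gene (highest other 46). In the injured region the real count at this step was 0 (highest other 10), which all 35 splits reach by construction, so that the count of splits says nothing there. Drawing the mice into 5 days at random, 1 of 100 draws called as many genes over the days, the real one, in the injured (9977 against at most 2258) and uninjured region (5375 against at most 2). With regions exchanged at random within mice, 3 of 100 draws, the real one among them, called as many lists as the real 102. This share is under 0.05, the threshold used for all splits, but without a margin. Chance is not firmly excluded, because the highest other draw also reached 102 and 0 of these lists held with an estimated correlation. For lists between days chance was not excluded: 33 of 100 draws called at least the 53 lists of the injured region (highest other 65), and 15 of 100 at least the 54 of the uninjured region (highest other 71).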
